A study of Homo sapiens with 2 samples.

How the data were processed

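MDA-MB-468, a human triple-negative breast cancer cell line, had been grown in 3D culture as control organoids and as organoids expressing A4-Fc. Per the labels, the organoids were dissociated with dispase and then trypsin, both arms were pooled with multiplexing tags, and 15000 cells were targeted with the Chromium Next GEM Single Cell 3' v3.1 chemistry. There was 1 gene expression library, and 1 culture per arm. The labels do not spell out A4-Fc. It is taken here, from background knowledge and from the name Alk that the tag table gives the arm, to be an Fc-fused ALK4 ectodomain that binds CRIPTO.

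The deposited matrices hold UMI counts per feature and cell, 1 matrix per arm, each with 36601 genes and 12 multiplexing tags. The values were whole numbers with no normalization. The submitters' processing notes name Cell Ranger and GRCh38 (hg38); the Cell Ranger version and its annotation release are not given in the sources used here. The arm of each matrix was taken from its name, the tag table and the tag counts inside it. The tag table gives another library identifier than the title of the tag library, so it may belong to another pool, but the most abundant tag of each matrix was the one the table gives that arm. The tag library was used only through the tag counts in these matrices.

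Cells were kept with at least 1000 UMIs, at least 500 genes and at most 20% of UMIs from mitochondrially encoded genes. This removed 96 of 6099 control barcodes and 65 of 4551 A4-Fc barcodes. Counts were summed over the cells of each arm and divided by the arm's total, on the usual CPM scale. The ratio of A4-Fc to control carries the exact conditional Clopper-Pearson 95% interval of both sums. Shares of cells carry exact Clopper-Pearson 95% intervals. With 1 culture per arm and cells that are not replicates, no p-value was computed, and all intervals cover counting error only. No ratio is given where both arms held 3 counts or fewer.

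A gene was called 1.5-fold apart by size alone, without a test, among genes with at least 20 CPM in either arm. For 33 gene lists, members needed at least 5 CPM in either arm, and a list needed at least 5 such members; 32 lists met this. Each list's median log2 ratio was placed as a percentile among 10000 random lists of the same size, matched on mean CPM in 20 bins. A percentile under 2.5 or over 97.5 is called outside. Members of a list are often expressed together, so random lists understate the spread of such a median.

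The genes named are the CRIPTO gene TDGF1, ACVR1B, HSPA5 and the IGHG genes, the 12 highest and the 12 lowest ratios among genes with at least 20 CPM and the same direction in G1, S and G2M cells, and the members of each list farthest from 1, namely 4 per list or up to 6 for a list outside. Genes named beyond that rule were chosen after their values were seen, and the text says so. Some genes that meet the rule are not reported here. The cell filter, the lists, this rule, the clustering and most alternatives were fixed before the data were examined.

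Cell cycle phases were scored with scanpy on cells thinned to 5000 UMIs. Clusters came from 2000 variable genes of log-transformed counts per 10000, 30 principal components, 15 exact nearest neighbours, a shared-neighbour Jaccard graph with edges above 1 in 15, and the Leiden algorithm at resolution 0.5, without integration because both arms shared 1 pool. A second clustering, chosen after seeing the data, left out the 152 genes at least 1.5-fold apart with at least 5 CPM, and clusters are numbered by it unless stated. Scrublet, run per arm with an expected rate of 5%, called 0 control and 2 A4-Fc cells, far below that rate, so its calls were not relied on. Doublets were kept and, as an alternative, the 5% of cells with the most UMIs were removed.

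Gene positions and types came from GENCODE 29 on GRCh38, matched by Ensembl ID; 34616 of the 36601 IDs had a position. For windows along chromosomes, genes with at least 20 CPM were taken in order in groups of 50, and each window's median log2 ratio was centred on the median of all genes. The windows that set cluster 5 against other control cells gave G1, S and G2M cells the same weights on both sides.

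Settings fixed beforehand for comparison were no cell filter, a stricter filter of 3000 UMIs, 1000 genes and 10% mitochondrial UMIs, 3 other scalings including TMM factors, the mean over cells, thinned cells, removal of Scrublet calls or of the cells with most UMIs, equal weights for phases, other CPM minimums (5, 20 or 50), a 2-fold rule, and clustering at resolutions 0.25 and 1.0 or without cell cycle or 1.5-fold genes. Added after seeing the data were removal of cells with over 10% of tag UMIs from the other arm's tag, equal weights for clusters, removal of cluster 5, and the second clustering.

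The procedure was tested on simulated sums: intervals had close to their nominal coverage, genes simulated at 2-fold passed the 1.5-fold rule, and genes simulated without a difference did not. These sums carried Poisson error alone, which the intervals assume. The coverage therefore says nothing about added spread between cells or cultures. A list simulated at a lower level was placed outside, as were 2 of the other 31 lists. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, scikit-learn 1.9.0, leidenalg 0.10.2, matplotlib 3.10.9, R 4.3.3 and edgeR 4.0.16 were used.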

Results

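Single-cell RNA was measured in MDA-MB-468 organoids, control and A4-Fc expressing, from 1 culture per arm. After filtering, 6003 control cells held 85778806 UMIs and 4486 A4-Fc cells held 61229829. Median depth was 12377 UMIs and 4409 genes per control cell, and 12002.5 UMIs and 4302 genes per A4-Fc cell. The median mitochondrial share was 6.71% and 6.63%. The comparison asks which transcripts and cell states differ between tumour organoids with and without A4-Fc, in a series about CRIPTO, uptake of extracellular vesicles and activation of fibroblasts. There were no replicates, so a difference between the 2 cultures cannot be set against the spread between cultures.

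The A4-Fc culture carried transcript of IGHG1, the gene of the IgG1 heavy chain constant region that Fc fusions use (chromosome 14, 105736343 to 105743071). It stood at 15.6 CPM (95% interval 14.7 to 16.7, 957 UMIs) in A4-Fc cells and 0.198 CPM (0.115 to 0.317, 17 UMIs) in control cells, a ratio of 78.9 (49.0 to 136). A UMI of it was found in 9.41% of A4-Fc cells and 0.233% of control cells, a background level, at median depths of 12002.5 and 12377 UMIs. If all A4-Fc cells had the mean level, 18.8% would hold a UMI, so the transcript was spread unevenly over these cells. IGHG2, IGHG3 and IGHG4 had 0 UMIs in both arms. TDGF1, which encodes CRIPTO (chromosome 3, 46574534 to 46582463), had 0 UMIs in control and 1 in A4-Fc cells, so no ratio can be given, and its transcript was at the limit of detection. ACVR1B, which encodes the activin receptor ALK4, had 12.7 CPM in control and 11.2 in A4-Fc cells (ratio 0.881, 0.799 to 0.970). HSPA5, an endoplasmic reticulum chaperone that binds CRIPTO at the cell surface, had a ratio of 0.997 (0.967 to 1.029).

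Of 9 clusters of cells, cluster 5 differed most in share between the cultures. It held 834 of 6003 control cells (13.9%, 13.0 to 14.8) and 75 of 4486 A4-Fc cells (1.67%, 1.32 to 2.09). These shares come from the clustering without genes at least 1.5-fold apart at 5 CPM or more, chosen after seeing the data. In the planned clustering with all variable genes, the matching cluster held 14.8% and 1.65%, and 873 of its 964 cells were shared. In control cells, cluster 5 had 304 CPM of the long noncoding RNA AL583785.1 against 11.8 in other cells. AARD stood at 202 against 20.2 CPM, IGF2BP3, an RNA-binding protein of fetal tissue and tumours, at 177 against 19.3, the small heat shock protein gene CRYAB at 151 against 20.5, and MMP7, the protease matrilysin, at 92.5 against 10.5. No fixed marker class named the cluster, so it is given by number. Cluster 3, high in the squamous gene S100A7 and the keratin gene KRT81, held 13.0% of control and 19.4% of A4-Fc cells, at median depths of 8721 and 8681 UMIs. In the planned clustering, the cluster high in S100A7 and KRT81 held 6.91% and 10.7%. Of its fixed markers, 4 of 7 luminal and 1 of 7 basal genes were at least 1.5-fold higher than in other cells. Its overlap with cluster 3 is not given here. Another cluster of the planned clustering was high in OLFML3, CPA4 and AREG. It held 6.66% (6.05 to 7.32) and 17.1% (16.0 to 18.2). These 3 genes were themselves at least 1.5-fold higher in A4-Fc cells.

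**Figure D1:**
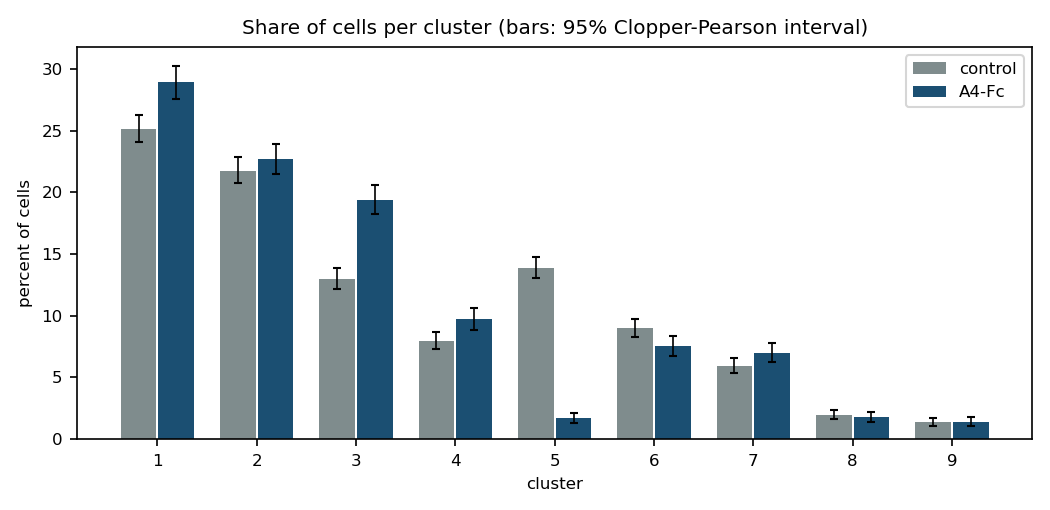
Percent of cells (vertical axis) in each of 9 clusters (horizontal axis) for the control (grey) and A4-Fc (blue) cultures, with exact 95% binomial intervals. Cluster 5 held 13.9% of control cells and 1.67% of A4-Fc cells.

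Cluster 5 also differed from other control cells over whole chromosome regions. In a window of chromosome 9 that ends at 75147265, in OSTF1, 49 of 50 genes were lower, with a median log2 ratio of −1.22. On chromosome X from 40648306 to 65534775 the median was −0.70, and on chromosome 2 from 218264123 to 237601614 it was −0.41. Of 136 windows, 6 lay beyond 0.3 in either direction, all of them lower. Genes of that chromosome 9 region made up a median 0.254% of the UMIs of a cluster 5 control cell and 0.655% in other control cells. With cluster 5 left out of both arms, the window farthest from 0 between A4-Fc and control stood at −0.05. Windows of cluster 4, which held mitotic genes such as UBE2C, also lay beyond 0.3 (49 of 136 in control cells), so that size alone is not particular to a region of altered copy number.

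**Figure D2:**
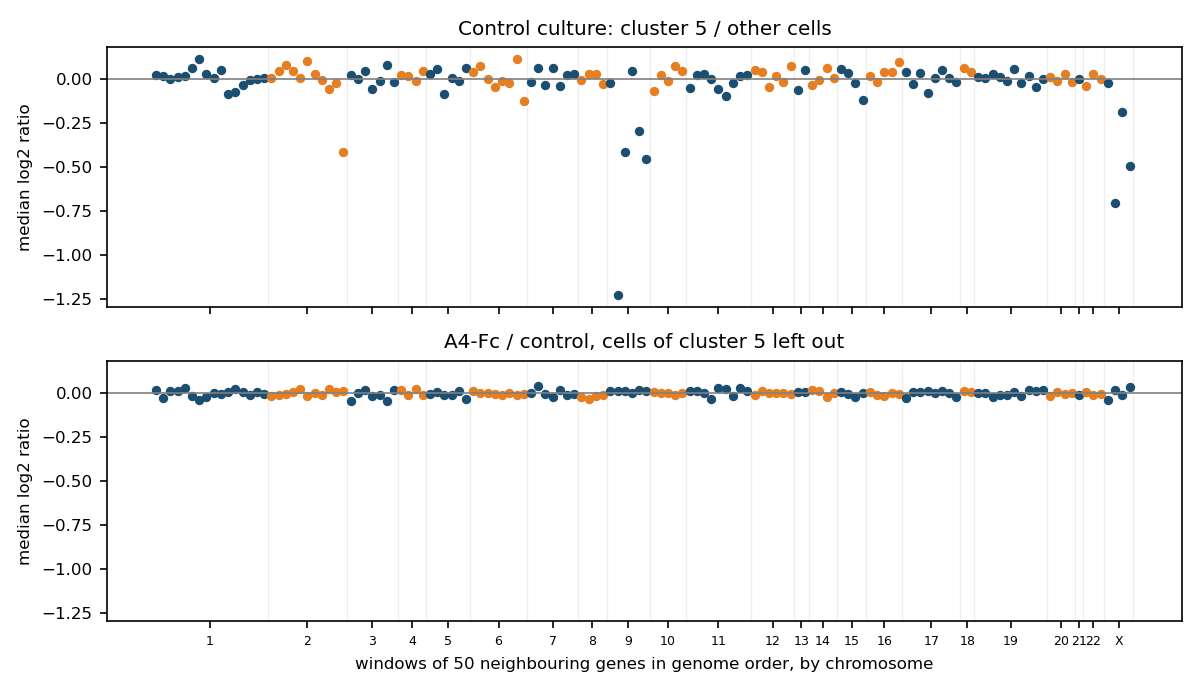
Median log2 ratio (vertical axis) of windows of 50 neighbouring genes in genome order (horizontal axis); each point is 1 window. In the upper panel, cluster 5 against other control cells, a chromosome 9 window reached −1.22; in the lower panel, A4-Fc against control without cluster 5, the window farthest from 0 stood at −0.05.

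Most genes were close to equal in the 2 cultures. Of 7422 genes with at least 20 CPM, 96.1% had ratios within 1.2-fold of 1, 13 were at least 1.5-fold higher in A4-Fc cells and 34 at least 1.5-fold lower. Without cluster 5, a comparison added after seeing the data, 8 were higher and 14 lower; 7 and 10 of these were among the genes called with all cells.

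Among genes with at least 20 CPM and the same direction in each phase, the lowest ratio was that of AL583785.1 (chromosome 9, 13446491 to 13487511), with 55.8 CPM in control and 6.50 in A4-Fc cells (ratio 0.117, 0.105 to 0.129), and 0.304 without cluster 5. AARD (chromosome 8, 116938199 to 116944487) had a ratio of 0.263 and 0.464 without cluster 5. CRYAB (chromosome 11, 111908565 to 111923722) had 0.293 and 0.492, MMP7 (chromosome 11, 102520508 to 102530753) had 0.299 and 0.517, and IGF2BP3 (chromosome 7, 23310209 to 23470467) had 0.353 and 0.640. For MME, the cell surface peptidase neprilysin, the values were 0.400 and 0.708, for SAA1, an acute-phase protein, 0.473 and 0.671, and for the transcription factor gene TFCP2L1 0.493 and 0.867. BST2, the interferon-induced protein tetherin that holds budding virus at the membrane (chromosome 19, 17402939 to 17405648), had 39.4 and 15.3 CPM, a ratio of 0.389 (0.361 to 0.418) and 0.406 without cluster 5. CP, the copper carrier ceruloplasmin, had 0.403 and 0.430, and HLA-B, a class I antigen-presenting molecule, 0.516 and 0.630. AARD, IGF2BP3, BST2, CP and HLA-B were lower in each of 8 clusters of the planned clustering with at least 200 cells per arm.

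Among the same genes, the highest ratio was that of KRT6A, a keratin of activated keratinocytes (chromosome 12, 52487174 to 52493257), with 10.5 CPM in control and 21.5 in A4-Fc cells (ratio 2.06, 1.89 to 2.24). OLFML3, a secreted matrix protein, had a ratio of 2.04 (1.90 to 2.18). AREG, the EGFR ligand amphiregulin (chromosome 4, 74445134 to 74455009), had 84.6 and 157 CPM, a ratio of 1.85 (1.80 to 1.91), and HBEGF, another EGFR ligand, had 16.0 and 26.3 CPM, a ratio of 1.64 (1.53 to 1.77). KLK6, a secreted serine protease, had 99.5 and 160 CPM, a ratio of 1.61 (1.57 to 1.66). EPHB6, a kinase-dead ephrin receptor, the potassium channel gene KCNQ5, the noncoding RNA RMRP, SPTSSB, the carboxypeptidase gene CPA4, the calpain gene CAPN8 and the antisense transcript PPP1R14B-AS1 had ratios from 1.51 to 1.66. Without cluster 5, AREG stood at 1.66, HBEGF at 1.55 and KLK6 at 1.56. AREG, HBEGF, KLK6 and OLFML3 were higher in each of the 8 clusters.

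**Figure D3:**
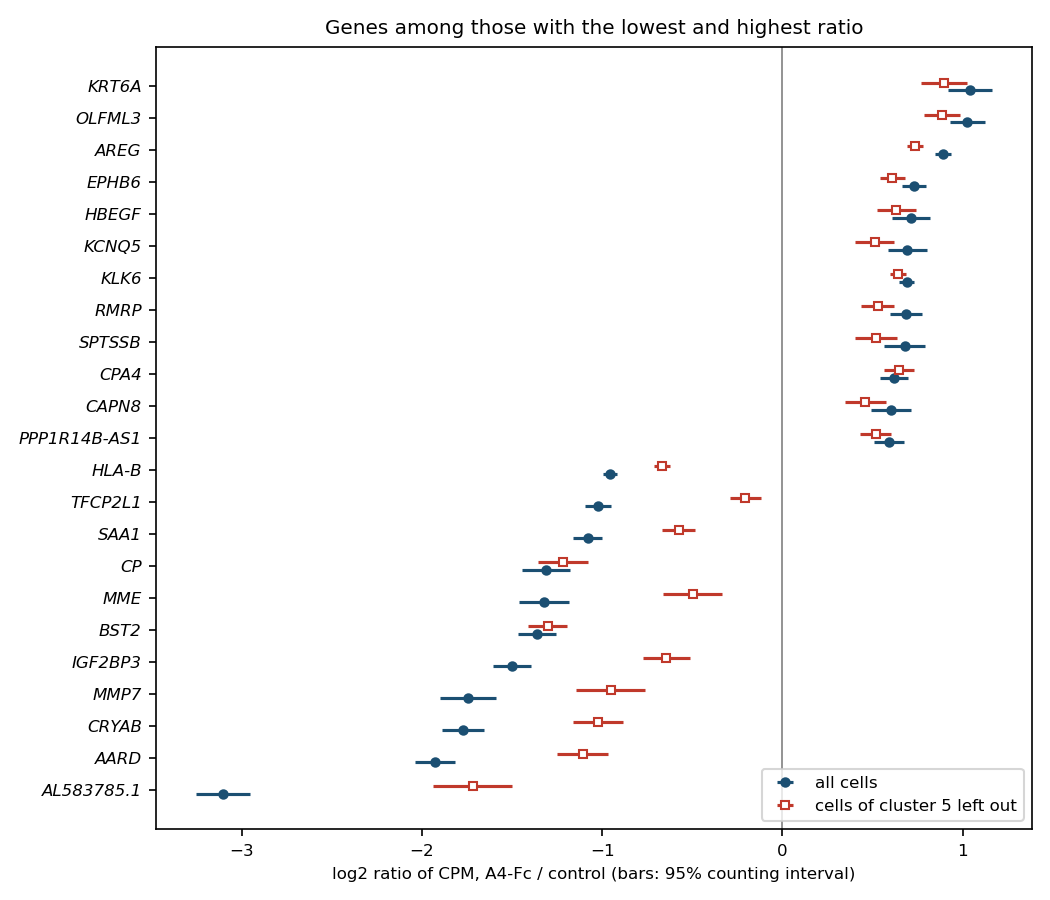
Log2 ratio of CPM, A4-Fc to control (horizontal axis), for genes among the 12 lowest and the 12 highest (vertical axis), with all cells (filled circles) and without cluster 5 (open squares); bars are 95% counting intervals. AL583785.1 had a ratio of 0.117 with all cells and 0.304 without cluster 5, and BST2 0.389 and 0.406.

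Interferon-response genes were lower in the A4-Fc culture. Of 24 measured members, 23 were lower and 1 higher, with a median log2 ratio of −0.32, below each of the 10000 random lists, and 8 were at least 1.5-fold lower. IFITM1, which blocks entry of viruses, had a ratio of 0.375 (0.319 to 0.439), IFI6 0.446, IRF9, the DNA-binding part of the interferon-activated complex, 0.477, the antiviral GTPase gene MX1 0.529 and IFIT3 0.589. The list's median lay below 0 in each of the 8 clusters, from −0.44 to −0.18, and was −0.31 without cluster 5. Antigen presentation genes were lower too, 12 of 13, with a median of −0.19, below each random list, and −0.13 without cluster 5. HLA-F had a ratio of 0.583, PSMB9, a subunit of the immunoproteasome, 0.769, HLA-C 0.770 and TAP1, a peptide transporter, 0.795. NF-kappaB response genes had 13 of 17 members lower and a median of −0.17, below each random list, with ratios of 0.554 for SAA2 and 0.646 for the adhesion molecule gene ICAM1. This median was −0.12 without cluster 5. SAA2 was high in cluster 5 (log2 ratio 2.18 against other control cells). Within the 8 clusters its log2 ratio between cultures ran from −0.83 to 0.004, while ICAM1 was lower in each.

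Basal and squamous keratinocyte genes were higher in the A4-Fc culture, 14 of 16, with a median of 0.15, above each random list, and 0.16 without cluster 5. IVL, which encodes involucrin of the cornified envelope, had a ratio of 1.81 (1.55 to 2.12), the basal keratin genes KRT14 and KRT5 1.36 and 1.22, and KRT16 1.35. Laminins, integrins and basement membrane genes had 10 of 16 members higher and a median of 0.07 (percentile 99.6), with ratios of 1.31 for LAMA3 and 1.28 for LAMB3. That median lay inside the random range with thinned cells (0.053) and among members with at least 20 CPM (0.021). LAMA3 was low in cluster 5 against other control cells, so the smaller share of that cluster may raise its ratio. Between cultures, LAMA3 was higher in 5 and lower in 3 of the 8 clusters, from −0.24 to 0.35. LAMB3 was higher in 6 and lower in 2. COL4A5 was higher and LAMA5 lower in each of the 8. Luminal and luminal progenitor genes had 9 of 16 lower and a median of −0.10 (percentile 0.05), with 0.588 for CD14, 0.707 for AGR2 and 0.732 for PROM1. This median was −0.05 (percentile 2.07) without cluster 5 and turned to 0.04 among members with at least 20 CPM. Mesenchymal genes had 6 of 8 lower and a median of −0.21, below each random list. FN1, the matrix protein fibronectin, had a ratio of 0.425 (0.377 to 0.477) and the intermediate filament gene VIM 0.772, while S100A4 had 1.35. Without cluster 5 the mesenchymal median was −0.05 (percentile 6.94), and among members with at least 20 CPM it was −0.064, also inside. Epithelial adhesion genes and keratins lay inside the random range (median −0.02, percentile 9.62, 12 of 23 lower), with a ratio of 0.552 for the tight junction gene CLDN1, and so did stem cell genes (median −0.02, percentile 25.7), with 0.692 for CD24 and 0.811 for SOX4. The stem cell median was −0.072, outside, among members with at least 20 CPM. CLDN1 was high in cluster 5 (log2 ratio 2.03 against other control cells). Between cultures it was lower in 5 and higher in 3 of the 8 clusters, from −1.10 to 0.13.

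The lists closest to the subject of the series were mostly near 0. Extracellular vesicle biogenesis and cargo genes had a median of 0.01 (percentile 72.6, 19 of 34 higher), with ratios of 1.32 for ANXA1, a membrane-binding annexin, and 0.875 for FLOT1. RAB27B, which acts in vesicle secretion, had 60.5 CPM in control and 72.5 in A4-Fc cells. Genes of vesicle uptake and endocytosis had a median of 0.01 (percentile 63.4, 17 of 30 higher), with ratios of 1.18 for the clathrin light chain gene CLTA and 0.852 for EEA1 of early endosomes. CAV1, which coats caveolae, had 68.0 and 85.3 CPM. ANXA1 and CLTA lie in the chromosome 9 region that was lower in cluster 5, and without that cluster they had 1.21 and 1.08. RAB27B was also low in cluster 5 (log2 ratio −1.15 against other control cells). Between cultures it was higher in 6 and lower in 2 of 8 clusters of the planned clustering. CRIPTO, nodal and activin signalling components had a median of −0.02 (percentile 35.9). The activin and inhibin subunit genes INHBB and INHBA had ratios of 0.737 and 1.24. INHBB was high in cluster 5 (log2 ratio 0.95 against other control cells). Between cultures, INHBB was lower in 6 and higher in 2 of the 8 clusters, and INHBA higher in 4 and lower in 4. The receptor gene TGFBR1 had 37.6 and 47.0 CPM. It was low in cluster 5 (log2 ratio −1.01 against other control cells), and between cultures higher in 7 and lower in 1 of the 8 clusters. SMAD2/3 target genes had a median of −0.01 (percentile 44.9), with 0.153 (0.127 to 0.183) for TIMP3, an inhibitor of matrix proteases high in cluster 5, and 0.162 without that cluster, at 3.39 and 0.550 CPM, 1.46 for SPHK1 and 0.738 for CCN2. Without cluster 5 the median of the SMAD2/3 target genes was 0.06, above the random range. BMP target genes had 5 of 7 lower and a median of −0.15 (percentile 0.34), but 0.01 (percentile 54.7) without cluster 5 and −0.050, inside the range, with thinned cells. BAMBI had a ratio of 0.738, and ID1 had 119.6 and 143 CPM. Against other control cells, cluster 5 had a log2 ratio of 0.98 for BAMBI and −1.88 for ID1. Between cultures, BAMBI was lower in 5 and higher in 3 of the 8 clusters, and ID1 higher in 5 and lower in 3.

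Secreted factors that can act on fibroblasts were lower for 10 of 12 members, with a median of −0.09 (percentile 1.34) and −0.08 without cluster 5. PDGFC and PDGFB, growth factors of the PDGF family, had ratios of 0.754 and 0.802, TGFB2 0.757, EDN1, which encodes endothelin, 0.762, and FGFBP1, which releases FGF from matrix, 1.11. The list's median lay below 0 in each of the 8 clusters, but inside the random range with the mean over cells (−0.057), with thinned cells (−0.097) and without the 5% of cells with most UMIs (−0.082). Output genes of Src, EGFR and MAPK signalling had a median of −0.03 (percentile 11.1) but a mean of 0.10, since AREG, HBEGF and EREG (ratio 1.51) were at least 1.5-fold higher while 13 of 23 members were lower. Without cluster 5 that median was −0.05 (percentile 0.38), outside the range. Matrix proteases and inhibitors had a median of 0.06 (just inside the random range) and a mean of −0.04, with KLK6 and KLK8 (1.35) higher and MMP7 lower. That median turned to −0.03 without cluster 5 and was 0.081, outside the range, with the mean over cells.

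Hypoxia response genes were lower for 18 of 20 members, with a median of −0.11, below each random list, and ratios of 0.734 for EGLN3, an oxygen-sensing hydroxylase, and 0.745 for DDIT4. ATF4 and amino acid response genes had 14 of 18 lower and a median of −0.10, below each random list, with 0.798 for STC2. YAP and TEAD targets had 10 of 12 lower and a median of −0.15 (percentile 0.02), but −0.008 (percentile 31.0) without cluster 5, with 0.811 for CRIM1. NRF2 and metal response genes had 12 of 18 lower and a median of −0.07 (percentile 0.60), with 0.550 for the aldo-keto reductase gene AKR1C2 and 0.818 for the ferritin gene FTH1. Fatty acid synthesis genes had 8 of 10 lower and a median of −0.08 (percentile 0.89), with 0.665 for the desaturase gene FADS1. FADS1 was high in cluster 5 (log2 ratio 1.94 against other control cells). It was lower in 5 and higher in 3 of 8 clusters of the planned clustering. Mitochondrially encoded transcripts had 10 of 13 lower and a median of −0.04 (percentile 1.49), inside the range without a cell filter (−0.031). Genes of the p53 response and arrest had 11 of 17 higher and a median of 0.05 (percentile 97.6), with 1.30 for the cell cycle inhibitor gene CDKN1A and 0.726 for GADD45B. This median lay inside the random range under 6 other settings, from 0.044 to 0.057, among them TMM factors and no cell filter. Inside the random range were glycolysis enzymes (median −0.02), the unfolded protein response (−0.01), immediate early and dissociation stress genes (0.01; KLF2 1.46, EGR1 0.839), cholesterol synthesis (−0.02), WNT pathway targets (−0.08, but −0.09 and outside without cluster 5; RNF43 0.728) and the Notch pathway (−0.06). Of the 32 lists, 13 lay below and 5 above the random range, where 1.6 would by chance if lists and their members were independent.

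**Figure D4:**
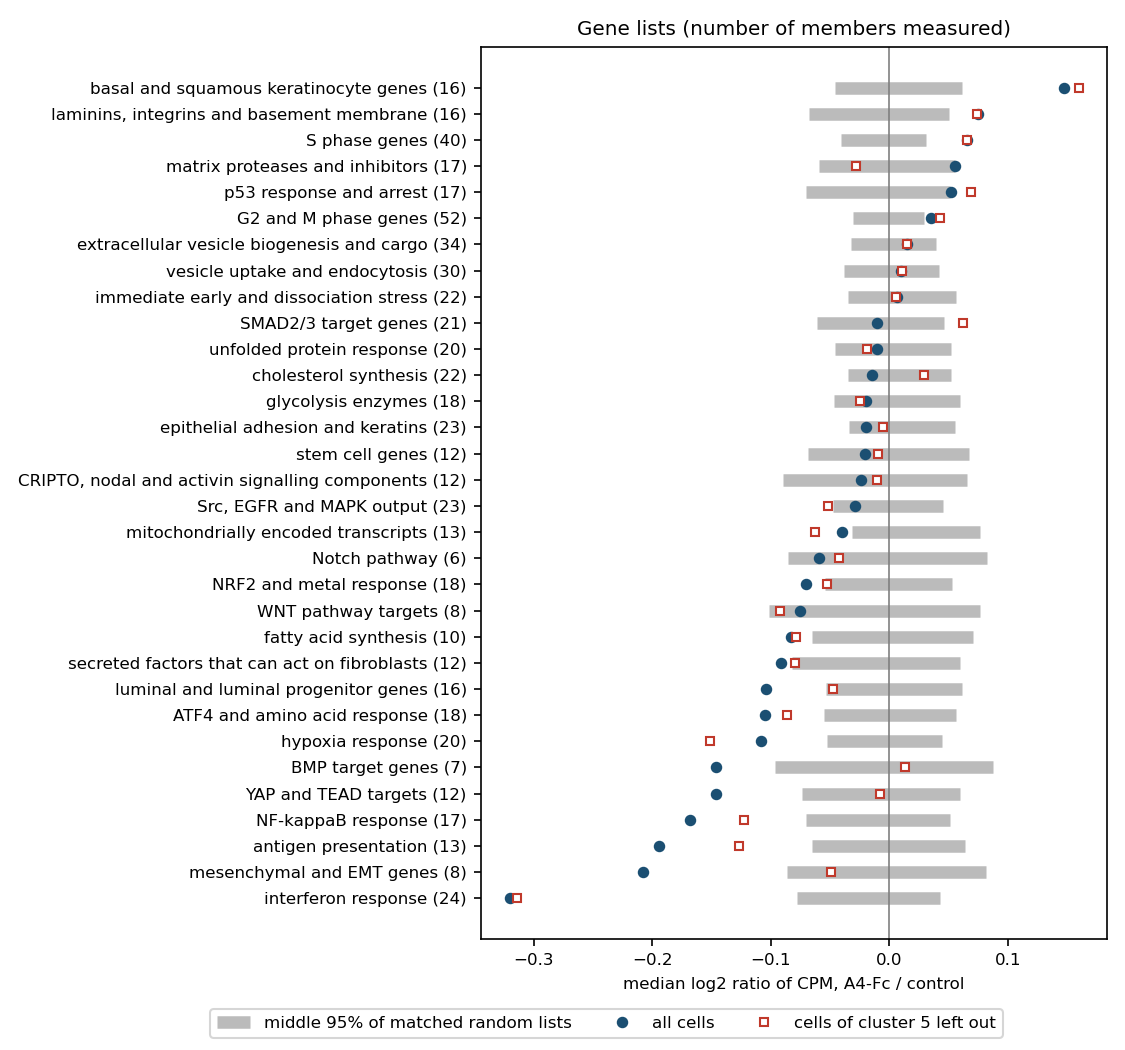
Median log2 ratio of CPM, A4-Fc to control (horizontal axis), for 32 gene lists (vertical axis), with all cells (filled circles) and without cluster 5 (open squares); grey bars hold the middle 95% of matched random lists for all cells. The interferon response stood at −0.32 and −0.31, and the basal and squamous keratinocyte genes at 0.15 and 0.16.

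S phase genes were slightly higher in the A4-Fc culture, 35 of 40, with a median of 0.07 (percentile 99.99), and G2 and M phase genes had 35 of 52 higher and a median of 0.04, above the random range but inside it with phases weighted equally (0.014). CCNE2, a cyclin of S phase entry, had a ratio of 1.27 (1.17 to 1.38). By scores on thinned cells, 49.4% of control cells (48.1 to 50.7) and 46.8% of A4-Fc cells (45.3 to 48.3) were in G1, 21.1% (20.1 to 22.2) and 23.3% (22.1 to 24.6) in S, and 29.4% and 29.9% in G2 or M. A UMI of the proliferation genes MKI67 or TOP2A was found in 39.7% (38.4 to 41.0) and 39.0% (37.5 to 40.4) of thinned cells. Scores lay near the threshold in 6.30% and 6.67% of cells, and free RNA in droplets can enter such scores, so the difference in phases remains open.

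Transcripts of other cell types were low in both cultures. COL1A1, a fibroblast collagen gene, had 10.0 CPM in control and 11.3 in A4-Fc cells, the endothelial gene PECAM1 2.66 and 4.67, and CD14, which luminal progenitors also express, 17.8 and 10.5. COL1A1 and PECAM1 are fixed cell type markers named beyond the rule, after their values were seen. The other markers of these cell types are not given here.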

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

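The test in this part was chosen after the tag counts were seen and before its own result was known. Tag counts enter no ratio or share of the report; they were used to remove cells in 1 alternative setting and to test cluster 5 cells, and both matrices held signal in tags other than their own. The other arm's tag had 529086 UMIs in control cells, 6.05% of the UMIs of both tags, and 311471 UMIs in A4-Fc cells, 6.54%. In no cell did the other arm's tag exceed the cell's own, but the tag counts themselves decided the matrix of each cell. That result therefore does not show that cells were placed in the right arm. Tags given to no arm had 111 UMIs in the control matrix and 76 in the A4-Fc matrix, above the 3 counts that a count of 0 allows. The 5% of control cells highest in the A4-Fc tag had 0.0646 times the IGHG1 level of the A4-Fc culture (95% interval 0.0133 to 0.189, 3 UMIs), which argues against A4-Fc cells making up a large part of those droplets.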

How the results depend on the processing

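The settings that removed cells by tag, removed cluster 5 or weighted clusters equally, and the second clustering, were chosen after seeing the data. Of the alternative values for list medians, 412 kept their side of the random range, 24 moved inside it, 9 moved outside it, and 2 turned the direction of a median that lay outside. Of the 412, 16 turned sign, all of them medians inside the range, such as matrix proteases and cholesterol synthesis without cluster 5, and so did 2 of the 9, both of SMAD2/3 targets. Of those for single genes, 215 stayed within the counting interval, 32 left it and 0 reversed, and all 10 for phase shares stayed within theirs. Except where stated, the cause was not tested. Counts of genes at least 1.5-fold higher and lower were 8 and 10 with clusters weighted equally, 8 and 14 without cluster 5, 52 and 100 at 5 CPM, 3 and 16 at 50 CPM, and 2 and 10 at 2-fold, where the last 3 follow from the rule itself. The largest difference in cluster share, A4-Fc minus control, was −8.04 points at resolution 1.0, where more clusters divide the cells, and −11.56 without genes at least 1.5-fold apart at 20 CPM or more, against −13.18; the second clustering, which used 5 CPM, gave −12.22.

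With clusters weighted equally and without cluster 5, in that order, the median was 0.054 and 0.062 for SMAD2/3 targets, −0.050 and −0.051 for Src, EGFR and MAPK output and −0.099 and −0.092 for WNT targets, all now outside the random range; it was −0.006 and 0.013 for BMP targets, the latter reversed, and −0.010 and −0.008 for YAP and TEAD targets, now inside. Mesenchymal genes had −0.049 without cluster 5, and p53 genes 0.044 with clusters weighted equally, both inside. With the mean over cells, BMP targets had −0.094, secreted factors −0.057 and G2 and M genes 0.023, all inside, and matrix proteases 0.081, outside. With thinned cells, BMP targets had −0.050, secreted factors −0.097 and laminins 0.053, all inside. Among members with at least 20 CPM, BMP targets had −0.052, mesenchymal genes −0.064 and laminins 0.021, all inside, stem cell genes −0.072, outside, and luminal genes 0.040, reversed. Without the cells with most UMIs, secreted factors had −0.082 and G2 and M genes 0.026; with phases weighted equally, G2 and M genes had 0.014 and p53 genes 0.051, all inside. Without a cell filter, mitochondrial transcripts had −0.031 and p53 genes 0.051, and after removal by tag −0.034 and 0.044, all inside. Scaled without mitochondrial and ribosomal protein genes, WNT targets had −0.116, outside, and p53 genes 0.050, inside; with TMM factors p53 genes had 0.057, inside. Removal of Scrublet calls took out 2 cells and says nothing about doublets. TDGF1, with 0 and 1 UMIs, could not be compared at this depth, and 1 culture per arm limits all comparisons.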

Other observations

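The tests in this part were chosen after the pattern each addresses was seen, except that random lists and equal weights for phases were set beforehand. Their own results were not known when they were chosen, apart from the scaling test of the interferon list, the test of tag calls and the test of neighbouring genes within cluster 5. The windows within A4-Fc cells and within other clusters were added after the first windows were seen.

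Within the control culture, several gene lists had higher medians in cluster 5 than in other control cells, and others had lower ones. No random lists were drawn for this comparison, so no list is called outside, and only some lists are given. YAP and TEAD targets were higher for 10 of 12 members (median log2 ratio 0.65), antigen presentation genes for 12 of 13 (0.60), and secreted factors that can act on fibroblasts for 9 of 12 (0.49), counting here and for all lists below only members with at least 5 CPM in either arm. With secreted factors at 5 CPM or more in cluster 5 or in other control cells, 13 of 16 were higher. FGF2, a fibroblast growth factor, stood at 18.1 against 1.98 CPM, and CSF1, a macrophage growth factor, at 11.4 against 1.95. Both lay below 5 CPM over all control cells. CXCL8 went the other way, with a log2 ratio of −1.58. These genes were chosen after their values were seen. Mesenchymal genes had a median of 0.43 (6 of 8 higher), NF-kappaB genes 0.37 (13 of 17), cholesterol synthesis 0.38 (16 of 22) and interferon-response genes 0.14 (15 of 23). Basal and squamous genes had −0.26 (10 of 15 lower), mitochondrially encoded transcripts −0.12 (13 of 13 lower) and hypoxia response genes −0.09 (15 of 20 lower). Of thinned cells, 53.5% (50.02 to 57.0) in cluster 5 and 48.8% (47.4 to 50.2) of other control cells were scored G1.

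For the share of cluster 5, 13.9% of control and 1.67% of A4-Fc cells, cells of another line in the control culture are argued against by EGFR, amplified in MDA-MB-468, at 1.47 times (1.46 to 1.48) its level in other control cells, and by SMAD4, lost in this line, at 0.775 CPM in cluster 5. The chromosome 9 window at −1.22 could come from a subclone that has fewer copies of this region. RNA does not measure copy number, and cluster 4 reached 0.75 in another region. The same window stood at −0.98 in the 75 A4-Fc cells of cluster 5 against other A4-Fc cells, without equal weights for phases. These 75 cells were placed in cluster 5 by their expression, jointly with control cells, so this value is not independent support. The median control tag share was 4.86% (3.53 to 6.45) in those 75 cells and 6.40% in other A4-Fc cells. Their medians of the A4-Fc tag were 958 (805 to 1089) and 927 UMIs. These values argue against control cells placed in the A4-Fc matrix on weak or mixed tag counts. They cannot exclude control cells that carried mostly the A4-Fc tag, since the tag counts themselves decided the matrix of each cell. Control cells mixed in before tagging cannot be told apart from A4-Fc cells, since IGHG1 at 0.202 times the level of other A4-Fc cells (0.0549 to 0.518) rests on 4 UMIs, and whether A4-Fc or the founding of the cultures set the share of these cells stays open with 1 culture per arm.

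The 12 genes lowest in the A4-Fc culture might share a source. A segment of other copy number that spans the 50 nearest measured genes of each is argued against as the whole source, since these neighbours had a median log2 ratio of 0.00838 between cultures (−0.03 to 0.03 over the 12 genes) and of 0.0103 between cluster 5 and other control cells (−0.04 to 0.05), where the 12 genes had a median of 2.81; smaller segments were not tested. For a subpopulation of control cells carrying them together, their mean pairwise correlation over control cells was 0.138. This was above all 1000 random sets matched on expression, the highest of which reached 0.0156. A pick on the ratio between cultures favours genes of cluster 5, which holds a larger share of control cells. The correlation is therefore not independent support for such a subpopulation. Cluster 5 is a candidate for that subpopulation, but BST2 and CP kept ratios of 0.406 and 0.430 without it. AL583785.1, AARD, CRYAB and MMP7 also stayed lower without it. In the 8 other large clusters of the planned clustering, AL583785.1, CRYAB and MMP7 were lower in 7 and AARD in 8. The log2 ratio of AL583785.1 ran from −3.70 to 0.75 over them. Cells of the same kind may thus remain outside cluster 5, which was not tested.

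The lower interferon response is not accounted for by the technical sources tested. A wrong scaling factor would move matched random lists alike, yet the list's median of −0.32 differed from theirs by −0.304, and the lowest of them reached −0.17. The list's median was at most −0.307 with phases or clusters weighted equally, and −0.296 without the 1% of cells highest in the list in each arm. Within the A4-Fc culture, 232 thinned cells with an IGHG1 UMI had a list median 0.211 above that of cells without one. The range over 2000 Poisson draws was −0.002 to 0.41. This argues against a lower level only in cells that carry the transcript. Cells without a UMI are not shown to lack A4-Fc, which may be secreted if it is the ectodomain fusion assumed here. A response of the whole culture to A4-Fc may remain as a hypothesis, and a difference between 2 cultures unrelated to A4-Fc stays open as well.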
